A study of Mus musculus with 8 samples.

How the data were processed

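Microvessels were isolated from mouse forebrain by homogenisation, density sedimentation and filtration, and 100 ng of total RNA was labelled with Cy5 or Cy3, per the labels' protocols. RNA of 2 ages was hybridised on each of 8 Agilent two-colour whole-genome arrays. The age in each channel, the replicate number and the dye exchange were taken from the labels, and each ratio's direction from the dyes given there. The deposited files are Agilent Feature Extraction output, 1 per array, with 44397 spots each; the file headers give version 10.5.1.1, whereas the submitters' processing notes name version 12.6. Per the file headers, the median spot signals, median local background signals and processed signals are intensity values on a linear scale, and the deposited log ratio is the log10 of the processed Cy5 over Cy3 signal. Within a small tolerance, 84.4% to 89.4% of the spots per array met this definition of the log ratio, and the others did not. The processed signals and log ratios of the P5/adult array of replicate 1 are rounded to fewer digits than those of the other arrays. The main values use the median signals.

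The analysis was run in R 4.3.3 with limma 3.58.1. For the 3 comparisons, the choices of test, samples, covariates, gene lists, named genes and alternatives were made before the data were examined, apart from the changes given here. The blood cell lists and several tests of explanations used in the closing part came after results had been seen, as stated there. The plan named mean spot signals, which the files used here do not hold, so median signals took their place. A further change altered the results. The plan was normexp background correction (offset 50) fitted on all spots. On the dye-exchanged P10/adult array of replicate 1 and the P5/P10 array of replicate 2, 4 and 7 spots had a recorded local background far above their signal, down to a difference of -273125.5. Fitted with them, the background standard deviation of those arrays came to between 655.77 and 2709.59, against 0.70 to 5.39 on the other arrays. After the first results had been seen, spots whose signal lay more than 100 below their background in either channel were given the array's median background for the correction and then left out. The results with the plan's own fit are given as an alternative, as is the analysis without these 2 arrays. With simulated signals, 7 such spots moved a fitted background standard deviation from 19.0 to 1717.5, for a true value of 20. An analysis with no background correction, fixed beforehand, needs no such fit, and its counts of called genes lay within 1.5 times those reported.

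Each array was normalized by loess (span 0.3) with control and outlier spots at weight 0, spots that Feature Extraction marked as outliers were left out, and spots of 1 probe were averaged. Of 39429 probes, 27427 had an accession that matched a mouse gene symbol in the RefSeq table given (assembly GRCm38.p6, used for names only), and 12002 did not and kept the file's accession. No coordinates are given, because the probe design names the build mm9. Probes were kept when well above background in every channel of at least 1 age (27190 probes, of which 81 lacked too many spots for the fit). A gene was represented by its probe of highest mean intensity, which gave 21941 genes, 15592 with a symbol. Probes of near-identical family members, such as the haemoglobin and stefin genes, may share target, so those genes are best read as families. Among the 21941 genes, 523 were not well above background in any channel of some age, none of them among the genes named here.

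Because ratios exist only within an array, the replicate block is part of the main fit. For each slide, the 4 ratios were fitted by least squares with the P5-adult and P10-adult differences and a dye term, and this gave 1 value per age and replicate. limma then fitted age and replicate, with 2 residual and 2.91 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg within each comparison. Slide equals replicate and every slide holds all ages, so the values per replicate are the values within a batch. The dye exchange counted as the same replicate. On simulated arrays with this design and 21941 genes, 97% of 4-fold, 57.8% of 2-fold and 6% of 1.5-fold changes were recovered in P5 against adult, and 6% of the calls were unchanged genes. In P10 against adult the recovered shares were 94.7%, 34.6% and 0%, with 8% unchanged among the calls. In P5 against P10 they were 94.2%, 30.4% and 0%, with 4.3% unchanged. In P5 against adult the simulation changed 199 or 200 genes of each size, whereas 53.1% of genes were called in the data. The adjusted threshold eases as more genes change, so the simulated shares do not carry over to the data. Ehd1, for example, passed in limma in P5 against adult at -0.31 (adjusted p = 0.0486).

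The 33 gene lists, written before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and beside it with an estimated correlation and with fry. fry tests whether a list's genes move one way on balance and does not compare them with other genes. Some genes are in more than 1 list, among them 6 of 12 venous and 5 of 23 tip cell genes. Sox17 is in the endothelial identity and Wnt lists, and Vegfc in the arterial and tip cell lists. Results of such lists are not independent. Estimated correlations rest on 2 residual degrees of freedom, and none of the calls held with them. The genes named are, per comparison, the 8 of highest and the 8 of lowest log2 ratio that passed with the same sign in both replicates and carry a regular symbol, a fixed panel of 12 barrier, vessel and proliferation genes, and up to 4 passing members of each called list in the called direction (up to 2 of a list that was not called). Not every gene this rule takes is reported here. Alternatives covered the background correction, the normalization within and between arrays, the filter on dim probes, outlier spots, the dye term, the replicate block, the arrays used, the probe rule, the moderation, the threshold, each replicate alone and the set test. Values are log2 ratios ± the standard error of the fit, with n = 2 replicates throughout. The fit shares its spread over all ages. A gene's standard error is therefore the same in every comparison and is not the spread of that comparison alone.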

Results

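Gene expression was measured in microvessels isolated from mouse forebrain at 3 ages: 5 days after birth (P5), 10 days after birth (P10) and adulthood. The preparation kept particles under 70 µm, so it was enriched in capillaries and other small vessels but could carry attached or co-sedimented cells. Total RNA of 2 ages was hybridised together on each of 8 two-colour arrays, with no common reference. Each of the 2 replicates filled 1 slide of 4 arrays: P5 against adult, P10 against adult, the same P10 and adult pair with the dyes exchanged, and P5 against P10. P5 RNA was labelled with Cy5 on every array that held it. Between 65.2% and 73.3% of the 43020 non-control spots were well above background per channel and array. The number of replicates, 2 per age, limits the precision, and the labels do not say whether replicates came from separate animals or pools. The p-values therefore measure only the spread between these samples, which may be technical.

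The 3 pairings fitted together on each slide. Across probes, which are not independent replicates, the P5/P10 array followed the difference of the P5/adult and P10/adult arrays with r = 0.954 and a slope of 1.036 on slide 1 and r = 0.967 and a slope of 0.936 on slide 2. The dye-exchanged P10 and adult arrays ran opposite to their partners (r = -0.882 on slide 1 and r = -0.915 on slide 2). The log2 ratios of the 2 replicates correlated across the 21941 genes tested at r = 0.901 for P5 against adult, r = 0.813 for P10 against adult and r = 0.8 for P5 against P10.

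**Figure D1:**
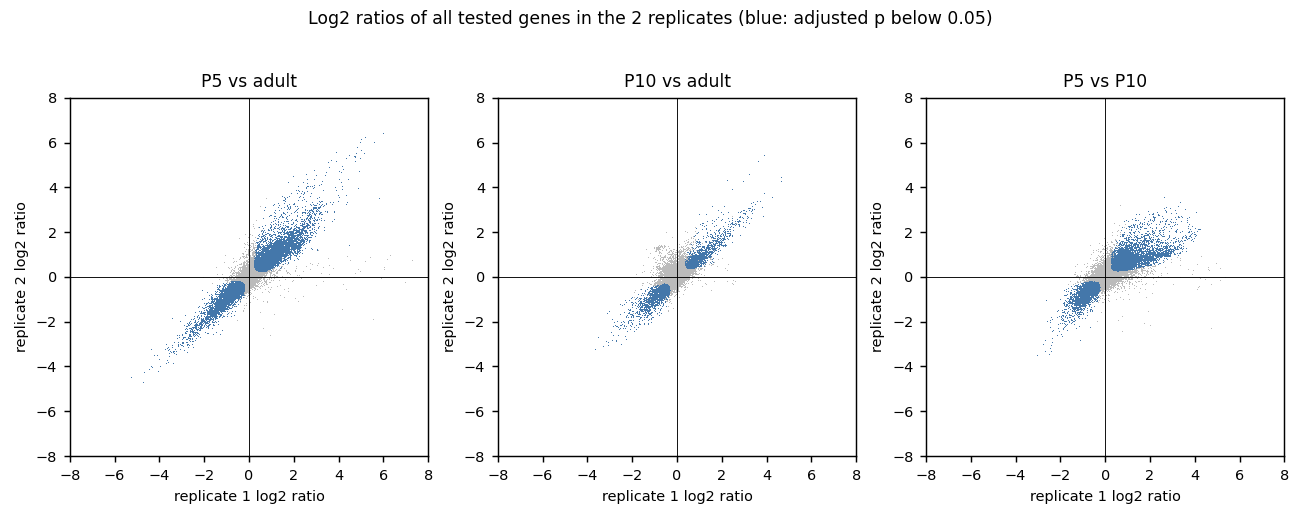
Log2 ratio of each tested gene in replicate 1 (x axis) and replicate 2 (y axis), 1 panel per comparison, with genes past the threshold in blue and the others in grey. The called genes lie in the quadrants where both replicates have the same sign, which passing the test all but requires. From left to right, r was 0.901, 0.813 and 0.8.

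The first comparison set P5 against adult microvessels. Genes of brain endothelium and of the blood-brain barrier were lower at P5, whereas genes of cell division, red blood cells and immature neurons were higher. Among the genes with the lowest ratios were Cxcl12, a chemokine (log2 ratio -4.88 ± 0.20 SE, n = 2, at its brighter probe and 0.02 at its other probe), Slco1a4, an organic anion transporter of brain endothelium (-4.48 ± 0.13), Ly6c1, an endothelial surface protein (-4.20 ± 0.12), and Flt1, a VEGF receptor (-3.86 ± 0.11). Degs2, Ndrg1, Prlr and Pmaip1 completed the 8 lowest, at -4.74, -4.14, -4.01 and -3.82. The 8 highest were the stefin family members Cstdc5 (6.19 ± 0.36), Stfa1 (5.77 ± 0.36) and Stfa2 (5.31 ± 0.33), the haemoglobin genes Hbb-bs (5.70 ± 0.29) and Hba-a2 (5.11 ± 0.20), the mitochondrial iron importer Slc25a37 (5.13 ± 0.22), Unc93a2 (5.31 ± 0.42) and Zdhhc22 (5.30 ± 0.35). Their adjusted p-values lay between 0.00053 and 0.0016. In all, 6598 genes were higher and 5049 lower at P5 than in adults at an adjusted p below 0.05, and 2795 and 1435 of these differed at least 2-fold. Every called gene had the same sign in both replicates, which passing this test with n = 2 all but requires.

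Endothelial genes fell as a group. Of the 22 measured members of the endothelial identity list, 21 were lower at P5 and none higher, with a median log2 ratio of -1.68 (-1.63 and -1.70 in the 2 replicates; camera adjusted p = 3.9e-12, and adjusted p = 0.395 with an estimated correlation). Besides Ly6c1 and Flt1, these included Ly6a (-3.71 ± 0.11) and Ptprb (-2.97 ± 0.13). The arterial and Notch list had 14 of 16 members lower and 1 higher, at a median of -1.44 (camera adjusted p = 1.67e-06, and adjusted p = 0.395 with an estimated correlation). Gkn3 (-2.96 ± 0.21), Mgp (-2.72 ± 0.20) and Vegfc (-2.06 ± 0.16) had the lowest ratios. The venous list was not called by camera (2 of 12 higher and 5 lower, median -0.15, adjusted p = 0.206); Ackr1, a chemokine-binding receptor of venules, was higher (2.15 ± 0.14) and Ephb4 lower (-1.25 ± 0.09). Mural cell genes were also lower: 11 of 14 pericyte genes (median -1.37, adjusted p = 2.11e-05) and 10 of 13 smooth muscle genes (median -1.84, adjusted p = 3.23e-05), each with adjusted p = 0.395 with an estimated correlation. Vtn (-2.42 ± 0.12), Atp13a5 (-2.13 ± 0.19), Tagln (-3.37 ± 0.25) and Myl9 (-2.78 ± 0.18) were among them. Pdgfrb, the PDGF receptor of pericytes, fell by 1.35 ± 0.14. In the same samples the median of the immature neuron list was 1.80 and that of the erythroid list 4.16.

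Barrier genes were lower at P5 in most of their lists. As in the other comparisons, the ratios are per total RNA of the fraction. The endothelial identity median of -1.68 was lower than the medians of the barrier lists called here. A smaller endothelial share at P5, as part of the cause, was therefore not separated from lower expression per endothelial cell. As the whole cause, it would lower transcripts made almost only by endothelial cells by a common factor. In P5 against adult, 8 such transcripts ranged from -2.52 to -0.35, with a median standard error of 0.121. These values argue against a smaller share as the whole cause, though no limit had been set for this comparison. Of 26 solute carriers of the barrier, 16 were lower and none higher (median -0.74, adjusted p = 3.17e-06). The glucose transporter Slc2a1 was at -3.32 ± 0.13 and the thiamine transporter Slc19a3 at -2.86 ± 0.13. Of 14 barrier enzymes, 9 were lower (median -1.45, adjusted p = 9.69e-05), among them Alpl (-3.38 ± 0.15) and the monoamine oxidase Maob (-3.00 ± 0.09). The tight junction list had 10 of 19 members lower and 5 higher (median -0.40, adjusted p = 0.0184). Ocln was at -2.18 ± 0.14, Lsr at -1.87 ± 0.11 and Cldn5 at -1.69 ± 0.11. The vesicular transport list had 8 of 14 lower and 2 higher (median -0.55, adjusted p = 0.0271). The caveola coat genes Cavin2 (-2.99 ± 0.09) and Cavin1 (-2.23 ± 0.15) were among the lower. Wnt signalling targets had 10 of 15 lower and 1 higher (median -0.91, adjusted p = 0.000101), including Sox17 (-2.39 ± 0.11), Foxq1 (-2.17 ± 0.10) and Lef1 (-1.56 ± 0.10). Each of these 5 lists had adjusted p = 0.395 with an estimated correlation. Efflux transporters were not called by camera (adjusted p = 0.322) but were by fry (down, adjusted p = 0.00343): 5 of 11 were lower and 4 higher, the median was 0.15 and the mean -0.60. The multidrug transporters Abcb1a (-3.11 ± 0.10) and Abcc4 (-2.72 ± 0.10) and the breast cancer resistance protein gene Abcg2 (-2.05 ± 0.13) were among the lower. The lipid transporter Mfsd2a was at -0.81 ± 0.14 (adjusted p = 0.0089) and the thyroid hormone transporter Slco1c1 at -1.47 ± 0.09. Plvap, a gene of fenestrated and immature vessels, did not pass (0.09 ± 0.16, adjusted p = 0.65).

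Cell cycle genes rose at P5, in 30 of 32 measured members (median 1.69, 1.84 and 1.57 in the 2 replicates; adjusted p = 2.59e-11, and adjusted p = 0.395 with an estimated correlation). Mki67, a marker of dividing cells, was at 4.80 ± 0.11, Ube2c at 3.96 ± 0.36 and Birc5 at 3.91 ± 0.15. Interstitial matrix genes were higher in 19 of 25 and lower in 1 (median 1.24, adjusted p = 5.86e-05, and adjusted p = 0.395 with an estimated correlation), including Mfap2 (2.99 ± 0.12), Fbn2 (2.57 ± 0.19) and the collagen gene Col3a1 (1.94 ± 0.15). Basement membrane genes went both ways, with 8 of 19 higher and 7 lower (adjusted p = 0.808; median 0.27, mean 0.00, tested direction down); Lamb1 was at 1.67 ± 0.14 and Lama5 at -1.52 ± 0.17, and Col4a1 did not pass (0.46 ± 0.16, adjusted p = 0.061). The tip cell list had 10 of 23 higher and 11 lower (median -0.25, adjusted p = 0.322), with Aplnr at 2.00 ± 0.12. Of the 21 measured extracellular proteases and inhibitors, 6 were higher and 7 lower (median -0.19, adjusted p = 0.398), with Reck at -1.93 ± 0.13 and Adamts1 at -1.92 ± 0.12. Imprinted growth genes were higher in 7 of 11 (median 0.86, 0.87 and 0.53 in the 2 replicates, adjusted p = 0.0291, and adjusted p = 0.522 with an estimated correlation), including Meg3 (2.98 ± 0.27) and Dlk1 (2.92 ± 0.77, 4.46 and 1.39 in the 2 replicates).

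Immune and stress-response genes were lower at P5. All 23 genes of antigen presentation and interferon response fell (median -1.89, adjusted p = 2.59e-11). They included Gbp2 (-3.37 ± 0.14) and Ifit1 (-3.29 ± 0.17). All 15 measured immediate early and stress genes fell (median -2.07, adjusted p = 3.63e-09). The phosphatase Dusp1 was at -3.57 ± 0.11, the flow-responsive factor Klf2 at -3.35 ± 0.14 and Nr4a1 at -2.89 ± 0.12. Endothelial activation genes were lower in 8 of 12 (median -0.84, adjusted p = 0.000309), with Nfkbia at -2.37 ± 0.11. All 3 had adjusted p = 0.395 with an estimated correlation. The endothelial identity median was -1.68 in the same samples. A smaller share of vessel cells at P5 may therefore contribute to these falls.

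Markers of other cell types moved with age as well. Erythroid genes were higher at P5 in all 13 measured members (median 4.16, adjusted p = 3.17e-06). For the globin genes Hba-a1, Hba-a2, Hbb-b2 and Hbb-bs, the fitted ratios were 4.94 to 5.70, but signal levels averaged over channels, which mix arrays and dyes, differed by only 3.94 to 4.53. Genes of immature neurons and progenitors were higher in 11 of 14, with 1 lower (median 1.80, adjusted p = 3e-05), among them Igfbpl1 (4.40 ± 0.24), Dcx (3.85 ± 0.21) and Sox11 (2.72 ± 0.10). Genes of myelinating oligodendrocytes were lower in 12 of 16 and higher in 1 (median -1.49, adjusted p = 3.17e-06), including Mal (-3.49 ± 0.14) and Mag (-2.62 ± 0.16). Each of these 3 lists had adjusted p = 0.395 with an estimated correlation. Mature neuron genes were lower in 8 of 16 and higher in 1 (median -0.42, adjusted p = 0.0271, and adjusted p = 0.522 with an estimated correlation), with Camk2a at -2.36 ± 0.20. The remaining lists were not called by camera. Of them, fry called oligodendrocyte precursors (up, adjusted p = 0.0112), glutamate genes (up, adjusted p = 0.0342), glycolysis (down, adjusted p = 0.0247) and perivascular macrophages (down, adjusted p = 0.0342). The mature neuron list, called by camera, was not called by fry (adjusted p = 0.0758). Oligodendrocyte precursor genes had 8 of 11 higher and 2 lower (median 0.93, adjusted p = 0.0575), astrocyte genes 3 of 16 higher and 5 lower (median -0.15, adjusted p = 0.301). Microglia genes had 4 of 14 higher (median 0.46, -0.08 and 0.98 in the 2 replicates, adjusted p = 0.197). Perivascular macrophage genes had 1 of 7 higher and 3 lower (median -0.15, adjusted p = 0.322), fibroblast genes 2 of 12 higher and 4 lower (median -0.10, adjusted p = 0.322). Choroid plexus and ependyma genes had 9 of 13 higher and 2 lower (median 0.94, adjusted p = 0.0985; up by camera and down by fry). Glutamate receptor and transporter genes had 13 of 24 higher and 5 lower (median 0.43, adjusted p = 0.192), glycolysis genes 3 of 16 higher and 8 lower (median -0.45, adjusted p = 0.0859). Oxidative phosphorylation genes had 2 of 28 higher and 4 lower (median 0.01, mean -0.06, adjusted p = 0.322).

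Adjusted over the list alone, the counts in P5 against adult were 13 of 14 higher for immature neurons, 9 of 11 higher and 1 lower for imprinted genes, 19 of 25 higher and 2 lower for interstitial matrix, and 9 of 19 higher for basement membrane. They were 8 of 21 lower for the proteases and inhibitors, 15 of 24 higher for glutamate genes, 10 of 13 higher for choroid plexus, 1 of 28 higher for oxidative phosphorylation and 0 of 14 for microglia. The counts of the lists not named here did not differ. Further probes of some genes named in this comparison gave smaller ratios in the same direction. The probe nearest 0 was at 2.88 for Slc25a37, -1.72 for Prlr, -0.65 for Cavin1, 3.18 for Ube2c, 0.97 for Birc5, 1.49 for Mfap2 and -1.10 for Reck. It was at -0.59 for Ephb4, -1.45 for Camk2a, 0.72 for Dcx, 2.18 for Meg3 and 1.13 for Dlk1. Median centring in place of loess lowered the medians of all 33 lists by 0.03 to 0.66, that of tight junctions from -0.40 to -0.99, and turned the sign for efflux, basement membrane, microglia and oxidative phosphorylation, none of them called. Fitting the background model to every spot, as planned at first, including the 11 with a faulty recorded background on 2 arrays, left 2769 higher and 2610 lower genes.

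**Figure D2:**
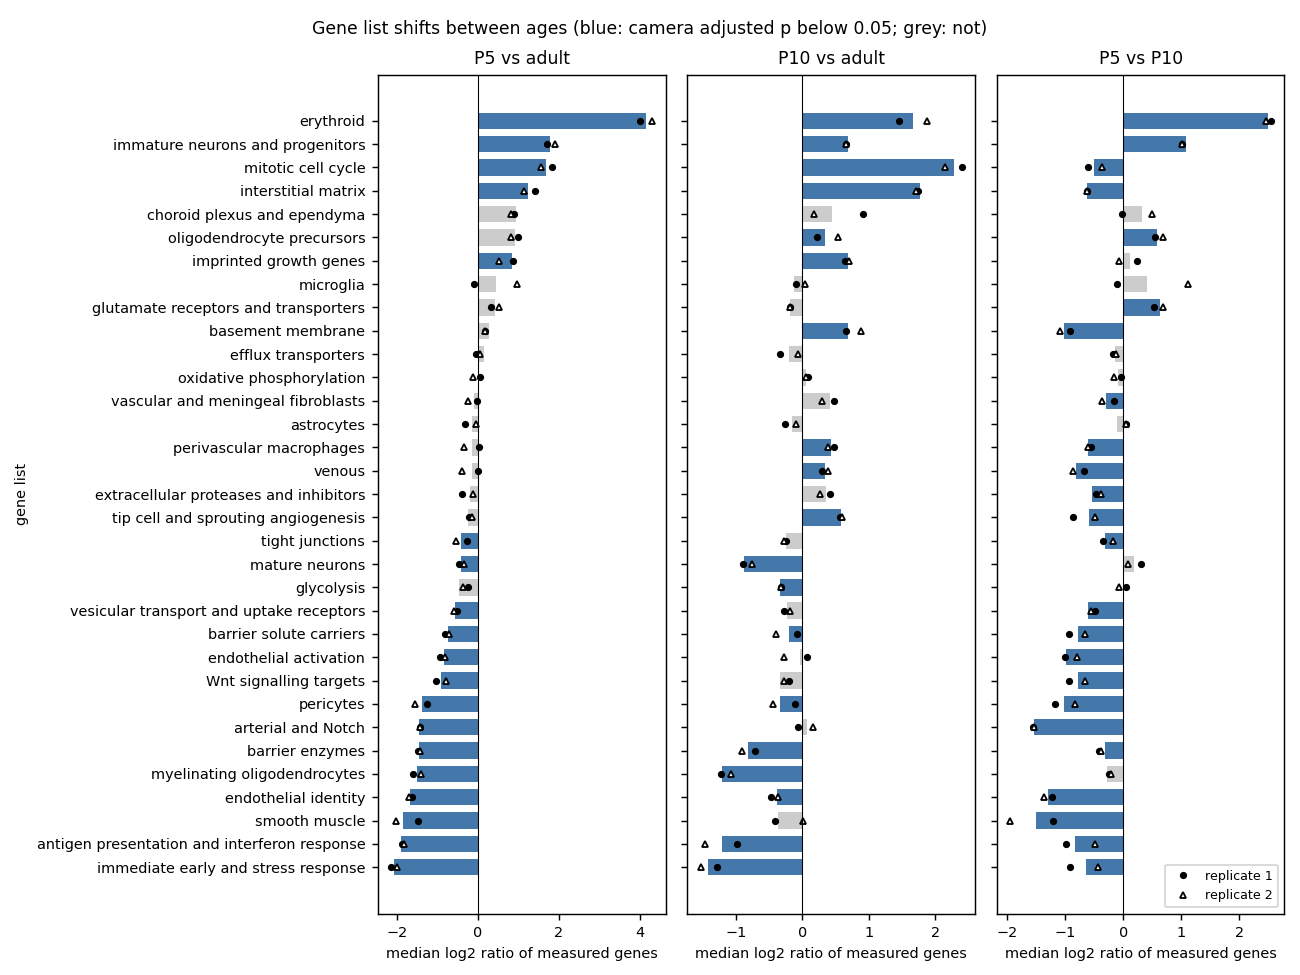
Median log2 ratio of the measured genes of each of the 33 gene lists (bars, x axis; blue where camera gave an adjusted p below 0.05 with the preset correlation, grey otherwise) in the 3 comparisons, with the median in replicate 1 as circles and in replicate 2 as triangles. The erythroid list reached 4.16 and the immediate early list -2.07 in P5 against adult.

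The second comparison set P10 against adult microvessels. Dividing-cell and matrix genes were higher at P10, and immune, stress-response, myelin and some barrier genes lower. The 8 highest were Cstdc5 (4.65 ± 0.36, n = 2), Mki67 (4.52 ± 0.11), the apoptosis inhibitor Birc5 (4.45 ± 0.15), Stfa1 (4.37 ± 0.36), the linker histone H1f5 (3.89 ± 0.21), Stfa2 (3.87 ± 0.33), the kinetochore gene Spc25 (3.80 ± 0.10) and Stfa2l1 (3.58 ± 0.31). The 8 lowest were Ndrg1 (-3.47 ± 0.17), the neuronal activity-regulated gene Arc (-3.12 ± 0.20), Sema3c (-3.10 ± 0.11), Cxcl12 (-3.04 ± 0.20), Xdh (-3.03 ± 0.13), Prlr (-2.87 ± 0.09), Pmaip1 (-2.81 ± 0.33) and Clic5 (-2.79 ± 0.11). The adjusted p-values of these 16 genes lay between 0.0017 and 0.0091. A further probe of Cxcl12 went the other way (0.78) and passed the threshold when all kept probes were tested. The value of Cxcl12 therefore rests on the brighter probe. The probe nearest 0 was at 1.86 for Birc5 and -1.60 for Prlr. The stefin values differed between the replicates: 3.89 and 5.40 for Cstdc5, 3.62 and 5.11 for Stfa1, 3.19 and 4.54 for Stfa2 and 2.93 and 4.23 for Stfa2l1. In replicate 1 all 4 lay below Mki67 (4.62) and Birc5 (4.64), so the ranking rests on replicate 2. In all, 1847 genes were higher and 1996 lower at P10, and 600 and 590 of these differed at least 2-fold.

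Cell cycle genes rose in 31 of 32 measured members (median 2.28, 2.40 and 2.15 in the 2 replicates; camera adjusted p = 1.64e-27, and adjusted p = 0.312 with an estimated correlation). Cenpe was at 3.34 ± 0.09 and Ccnb1 at 3.28 ± 0.10 (1.14 at its lowest probe). Interstitial matrix genes rose in 22 of 25 (median 1.77, adjusted p = 4.07e-19), led by Col3a1 (2.88 ± 0.15), Mfap2 (2.55 ± 0.12, and 1.58 at its other probe), Col1a1 (2.40 ± 0.09) and the elastic fibre gene Fbln5 (2.23 ± 0.18, and 0.72 at its other probe). Basement membrane genes rose in 11 of 19 (median 0.68, adjusted p = 2.35e-07), with Col18a1 at 2.46 ± 0.13, Lamb1 at 2.12 ± 0.14 and Col4a1 at 1.93 ± 0.16. Tip cell genes were higher in 11 of 23 and lower in 2 (median 0.58, adjusted p = 0.000447), with the apelin receptor Aplnr at 2.76 ± 0.12 and its ligand Apln at 2.60 ± 0.31. All 3 had adjusted p = 0.312 with an estimated correlation. The proteases and inhibitors were not called by camera (5 of 21 higher and 4 lower, median 0.35, adjusted p = 0.0522) but were by fry (up, adjusted p = 0.0189), with Timp1 at 2.46 ± 0.12 and Adamts9 at 2.03 ± 0.12. Imprinted growth genes were higher in 4 of 11 (median 0.68, adjusted p = 0.013, and adjusted p = 0.481 with an estimated correlation), with Mest at 2.31 ± 0.25 (0.82 at its lowest probe) and Plagl1 at 2.27 ± 0.22, the highest of its 4 probes (lowest 0.06).

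Endothelial identity genes were lower in 8 of 22 and higher in 1 at P10 (median -0.38, adjusted p = 1.46e-05, and adjusted p = 0.312 with an estimated correlation). Flt1 (-2.42 ± 0.11), Ly6a (-2.32 ± 0.11), Ly6c1 (-2.29 ± 0.12) and Emcn (-1.64 ± 0.10) were lowest. Barrier enzymes were lower in 8 of 14 and higher in 1 (median -0.82, adjusted p = 0.000391, and adjusted p = 0.312 with an estimated correlation), including Alpl (-2.71 ± 0.15), Ddc (-2.02 ± 0.19) and Maob (-1.78 ± 0.09). Solute carriers were lower in 9 of 26 and higher in 4 (median -0.20, -0.08 and -0.39 in the 2 replicates, adjusted p = 0.0355, and adjusted p = 0.588 with an estimated correlation), with Slco1a4 at -2.10 ± 0.13 and Slc2a1 at -1.56 ± 0.13. Tight junction genes (4 of 19 lower, median -0.25, adjusted p = 0.0635), vesicular transport genes (3 of 14 higher and 4 lower, median -0.23, adjusted p = 0.224), efflux transporters (1 of 11 higher and 4 lower, median -0.20, adjusted p = 0.135) and Wnt targets (1 of 15 higher and 2 lower, median -0.34, adjusted p = 0.0522) were not called by camera, though fry called the efflux list (down, adjusted p = 0.00753). Among their members, Abcb1a fell by 1.71 ± 0.10, Lef1 by 1.08 ± 0.10, Ocln by 0.67 ± 0.14 and Slco1c1 by 0.67 ± 0.09, whereas Abca1 rose by 1.70 ± 0.11 and Sp5 by 1.15 ± 0.11. Abcg2 was lower in both replicates (-0.98 and -1.02, adjusted p = 0.012). Cldn5 missed the threshold narrowly (-0.46 ± 0.11, adjusted p = 0.0501) and Mfsd2a did not pass (-0.14 ± 0.14, adjusted p = 0.59). Plvap rose by 0.83 ± 0.16 (adjusted p = 0.032).

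The arterial and Notch list was not called by camera at P10 (2 of 16 higher, median 0.07, adjusted p = 0.359), with the gap junction genes Gja5 (1.91 ± 0.15) and Gja4 (1.69 ± 0.16) higher. Venous genes were higher in 5 of 12 and lower in 1 (median 0.34, adjusted p = 0.0427, and adjusted p = 0.531 with an estimated correlation). Pericyte genes were lower in 4 of 14 (median -0.34, -0.11 and -0.44 in the 2 replicates, adjusted p = 0.0355, and adjusted p = 0.534 with an estimated correlation), with Vtn at -1.18 ± 0.12, while Pdgfrb did not pass (0.05 ± 0.14, adjusted p = 0.87). Smooth muscle genes were not called by camera (1 of 13 higher and 4 lower, median -0.37, adjusted p = 0.121).

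Immune genes were lower at P10 in 17 of 23 members of the antigen presentation and interferon list (median -1.21, adjusted p = 9.03e-13), with Ifit1 at -2.50 ± 0.17, Gbp2 at -2.00 ± 0.14 and B2m at -1.71 ± 0.14. Immediate early and stress genes were lower in 11 of 15 (median -1.41, adjusted p = 4.16e-11), including Dusp1 (-2.35 ± 0.11), Nr4a1 (-2.24 ± 0.12) and the heat shock gene Hspa1a (-2.22 ± 0.13). Both had adjusted p = 0.312 with an estimated correlation. Endothelial activation genes were not called by camera (3 of 12 lower, median -0.04, adjusted p = 0.224). Glycolysis genes were lower in 2 of 16 (median -0.33, adjusted p = 0.00535, and adjusted p = 0.312 with an estimated correlation), and oxidative phosphorylation genes were not called by camera (1 of 28 lower, median 0.05, adjusted p = 0.613).

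Among markers of other cell types, myelinating oligodendrocyte genes were lower in 13 of 16 (median -1.20, adjusted p = 2.83e-09, and adjusted p = 0.312 with an estimated correlation), with Mag at -1.93 ± 0.16 and Mal at -1.78 ± 0.14. Mature neuron genes were lower in 9 of 16 (median -0.87, adjusted p = 5.42e-06, and adjusted p = 0.354 with an estimated correlation), with Camk2a at -1.84 ± 0.20. Immature neuron genes were higher in 9 of 14 (median 0.69, adjusted p = 0.000111, and adjusted p = 0.312 with an estimated correlation) and erythroid genes in 7 of 13 (median 1.67, adjusted p = 2.25e-05, and adjusted p = 0.452 with an estimated correlation). Smaller shifts were called for oligodendrocyte precursors (4 of 11 higher and 1 lower, median 0.34, 0.22 and 0.53 in the 2 replicates, adjusted p = 0.0422, and adjusted p = 0.354 with an estimated correlation) and perivascular macrophages (3 of 7 higher and 1 lower, median 0.43, adjusted p = 0.0187, and adjusted p = 0.312 with an estimated correlation). Astrocyte genes (1 of 16 higher and 3 lower, median -0.15, adjusted p = 0.166), microglia genes (0 of 14 past the threshold, median -0.13, adjusted p = 0.876) and fibroblast genes (3 of 12 higher and 1 lower, median 0.42, adjusted p = 0.122) were not called by camera. Neither were choroid plexus and ependyma genes (5 of 13 higher and 2 lower, median 0.45, adjusted p = 0.0793; up by camera and down by fry) or glutamate receptor and transporter genes (3 of 24 higher and 6 lower, median -0.18, adjusted p = 0.0914).

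Of the lists called by camera in P10 against adult, fry did not call solute carriers, venous, pericyte, erythroid and imprinted genes (adjusted p = 0.067 to 0.112). Adjusted over the list alone, the called lists in P10 against adult had 32 of 32 higher for the cell cycle, 25 of 25 for interstitial matrix, 13 of 19 for basement membrane, 12 of 23 for tip cell genes (3 lower). They also had 6 of 11 for imprinted genes, 6 of 12 for venous genes, 8 of 13 for erythroid genes and 5 of 7 for perivascular macrophages. Lower were 21 of 23 interferon, 15 of 15 immediate early, 11 of 22 endothelial identity, 9 of 14 barrier enzyme genes. Also lower were 11 of 26 solute carrier (6 higher), 5 of 14 pericyte, 11 of 16 mature neuron and 5 of 16 glycolysis genes. Among lists not called, the counts adjusted over the list alone were 3 higher and 8 lower for tight junctions, 2 and 4 for efflux, 4 and 4 for vesicular transport, 3 and 8 for Wnt targets. They were 8 and 4 for the proteases and inhibitors, 4 and 7 for glutamate genes, 5 and 2 for arterial genes, 4 and 2 for fibroblasts, 2 and 3 for astrocytes, 1 and 4 for endothelial activation and 0 for oxidative phosphorylation. The counts of the lists not named here did not differ. The gene counts of this comparison depended on the processing more than those of P5 against adult: median centring in place of loess left 666 higher and 613 lower genes, the background model fitted to every spot left 101 and 152, and the 6 arrays without the 2 with faulty background spots left 852 and 1033. Leaving out the replicate block, with the 8 arrays as independent ratios, gave 4931 and 5037.

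The third comparison set P5 against P10 directly. Between these ages the genes of arteries, smooth muscle, endothelium and vascular matrix were lower at P5, and red cell and immature neuron genes higher. The 8 lowest were the arterial gap junction gene Gja5 (-3.30 ± 0.15, n = 2), Fbln5 (-3.02 ± 0.18, and -0.82 at its other probe), the smooth muscle genes Tagln (-3.00 ± 0.25) and Myl9 (-2.77 ± 0.18), Aoc3 (-2.88 ± 0.23), Mgp (-2.86 ± 0.20), the hedgehog ligand Dhh (-2.77 ± 0.10) and Gkn3 (-2.75 ± 0.21). The 8 highest were Unc93a2 (3.45 ± 0.42, 4.05 and 2.85 in the 2 replicates), Hbb-bs (3.31 ± 0.29), Zdhhc22 (3.26 ± 0.35), Slc25a37 (3.18 ± 0.22, and 2.14 at its other probe), the netrin receptor Dcc (3.15 ± 0.54, 4.2 and 2.11 in the 2 replicates, and 0.26 at its other probe), Rhox8 (3.06 ± 0.57, 4.09 and 2.02 in the 2 replicates, and 0.38 at its other probe), Hbb-b2 (3.02 ± 0.21) and Pigr (2.96 ± 0.58, 4.07 and 1.84 in the 2 replicates). Their adjusted p-values lay between 0.004 and 0.019. In all, 5041 genes were higher and 3993 lower at P5 than at P10, and 1998 and 630 of these differed at least 2-fold.

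All 22 endothelial identity genes were lower at P5 (median -1.30, -1.23 and -1.37 in the 2 replicates; camera adjusted p = 9.36e-13). Ptprb (-1.99 ± 0.13), Sox17 (-1.99 ± 0.11), Ly6c1 (-1.91 ± 0.12) and the angiopoietin receptor Tek (-1.73 ± 0.10) were lowest. The arterial and Notch list had 15 of 16 members lower and 1 higher (median -1.54, adjusted p = 1.32e-08), and 9 of 13 smooth muscle genes (median -1.51, adjusted p = 4.97e-06) and 11 of 14 pericyte genes (median -1.02, adjusted p = 1.08e-05) were lower. Each of these 4 lists had adjusted p = 0.338 with an estimated correlation. Vegfc was at -2.64 ± 0.16, Myh11 at -2.05 ± 0.25, Art3 at -1.54 ± 0.19 and Pdgfrb at -1.40 ± 0.14. Venous genes were lower in 7 of 12 and higher in 1 (median -0.82, adjusted p = 0.0119, and adjusted p = 0.405 with an estimated correlation), with Vwf at -1.38 ± 0.27. In the same samples the median of the immature neuron list was 1.08 and that of the erythroid list 2.50. Fibroblast genes were lower in 4 of 12 (median -0.30, -0.16 and -0.37 in the 2 replicates, adjusted p = 0.0392, and adjusted p = 0.392 with an estimated correlation), with Fmod at -1.52 ± 0.10.

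Barrier lists were lower at P5 than at P10 too. Solute carriers fell in 18 of 26 (median -0.77, adjusted p = 2.56e-08), with Slco1a4 at -2.38 ± 0.13 and Slc2a1 at -1.77 ± 0.13. Wnt targets fell in 11 of 15 (median -0.78, adjusted p = 7.8e-05), with Foxq1 at -1.29 ± 0.10. Barrier enzymes fell in 6 of 14 (median -0.32, adjusted p = 0.00215), vesicular transport genes in 8 of 14 with 1 higher (median -0.61, adjusted p = 0.00227), and tight junction genes in 9 of 19 with 3 higher (median -0.32, -0.34 and -0.17 in the 2 replicates, adjusted p = 0.0222). All 5 had adjusted p = 0.338 with an estimated correlation. Ocln was at -1.51 ± 0.14, Lsr at -1.40 ± 0.11, Abcb1a at -1.40 ± 0.10, Cldn5 at -1.23 ± 0.11 and Abcg2 at -1.05 ± 0.13. Slco1c1 fell by 0.80 ± 0.09, Plvap by 0.74 ± 0.16, Mfsd2a by 0.67 ± 0.14 and Lef1 by 0.47 ± 0.10. The efflux list was not called by camera (2 of 11 higher and 5 lower, median -0.14, adjusted p = 0.165) but was by fry (down, adjusted p = 0.0115), with Abcc4 at -1.53 ± 0.10 and Abcc5 at 1.47 ± 0.16 (0.64 at its lowest probe).

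Matrix, tip cell and cell cycle lists were also lower at P5 than at P10. Basement membrane genes fell in 14 of 19 (median -1.02, adjusted p = 2.74e-08), with Col18a1 at -1.92 ± 0.13, the fibronectin gene Fn1 at -1.81 ± 0.10 and Col4a1 at -1.47 ± 0.16. Interstitial matrix genes were lower in 13 of 25 and higher in 4 (median -0.63, adjusted p = 0.000437), tip cell genes lower in 11 of 23 and higher in 2 (median -0.59, adjusted p = 4.24e-06), and proteases and inhibitors lower in 12 of 21 and higher in 1 (median -0.53, adjusted p = 0.000173). Each of these 4 lists had adjusted p = 0.338 with an estimated correlation. Fbln2 was at -2.13 ± 0.14, the elastin gene Eln at -1.71 ± 0.15, Igfbp3 at -1.77 ± 0.10 and Angpt2 at -1.29 ± 0.10. Cell cycle genes were lower in 20 of 32 (median -0.51, adjusted p = 4.24e-06, and adjusted p = 0.392 with an estimated correlation), with Top2a at -0.91 ± 0.10, while Mki67 did not pass (0.28 ± 0.11, adjusted p = 0.092).

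Interferon genes were lower in 14 of 23 (median -0.83, -0.99 and -0.48 in the 2 replicates, adjusted p = 4.97e-06), immediate early genes in 8 of 15 (median -0.64, adjusted p = 4.39e-05) and endothelial activation genes in 7 of 12 (median -0.98, adjusted p = 0.000567). Gbp3 was at -1.50 ± 0.14, Klf2 at -1.72 ± 0.14 and Icam1 at -1.42 ± 0.18. Perivascular macrophage genes were lower in 4 of 7 (median -0.61, adjusted p = 0.000789), including Cbr2 (-1.57 ± 0.10). All 4 had adjusted p = 0.338 with an estimated correlation. Erythroid genes were higher in 12 of 13 (median 2.50, adjusted p = 4.24e-06), immature neuron genes in 11 of 14 with 1 lower (median 1.08, adjusted p = 4.44e-05), each with adjusted p = 0.338 with an estimated correlation. Glutamate receptor and transporter genes were higher in 15 of 24 with 1 lower (median 0.63, adjusted p = 0.000924), again with adjusted p = 0.338 with an estimated correlation. Igfbpl1 was at 2.53 ± 0.24, Dcx at 2.07 ± 0.21 (0.52 at its lowest probe) and Gria2 at 2.16 ± 0.17 (0.72 at its other probe). Oligodendrocyte precursor genes were higher in 7 of 11 and lower in 1 (median 0.59, adjusted p = 0.0319, and adjusted p = 0.338 with an estimated correlation); their median was -0.01 with median centring in place of loess. Genes of astrocytes (3 of 16 higher and 3 lower, median -0.11, mean 0.01, adjusted p = 0.83), microglia (3 of 14 higher, median 0.41, -0.10 and 1.12 in the 2 replicates, adjusted p = 0.0814) and myelinating oligodendrocytes (3 of 16 higher and 4 lower, median -0.28, adjusted p = 0.112) were not called by camera. Neither were those of mature neurons (6 of 16 higher, median 0.18, adjusted p = 0.375), choroid plexus and ependyma (2 of 13 higher and 1 lower, median 0.33, adjusted p = 0.701; up by camera and down by fry), imprinted growth (2 of 11 higher, median 0.11, adjusted p = 0.52), glycolysis (4 of 16 higher and 1 lower, median 0.00, adjusted p = 0.83) and oxidative phosphorylation (3 of 28 lower, median -0.09, adjusted p = 0.166).

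Adjusted over the list alone, the counts in P5 against P10 were 25 of 32 lower for the cell cycle, 17 of 19 for basement membrane, 15 of 25 with 5 higher for interstitial matrix, 15 of 23 for tip cell genes. They were 15 of 21 lower for the proteases and inhibitors, 7 of 7 for perivascular macrophages, 9 of 14 with 2 higher for vesicular transport, 8 of 12 for endothelial activation and 0 of 28 for oxidative phosphorylation. Higher were 13 of 14 immature neuron, 13 of 13 erythroid, 8 of 11 oligodendrocyte precursor, 15 of 24 glutamate (2 lower) and 0 of 13 choroid plexus genes. The counts of the lists not named here did not differ. The background model fitted to every spot, as planned at first, gave 0 higher and 0 lower genes in limma at an adjusted p below 0.05 (7065 at an unadjusted p below 0.05). The directly hybridised pair alone gave 2403 higher and 1597 lower, the 6 arrays without the 2 with faulty background spots gave 3305 and 2306, and median centring in place of loess turned the share of higher genes among the calls from 55.8% to 39.9% and lowered the medians of all 33 lists by 0.22 to 0.77. With it the medians of mature neurons, microglia, choroid plexus and imprinted genes, none of them called, also turned negative.

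**Figure D3:**
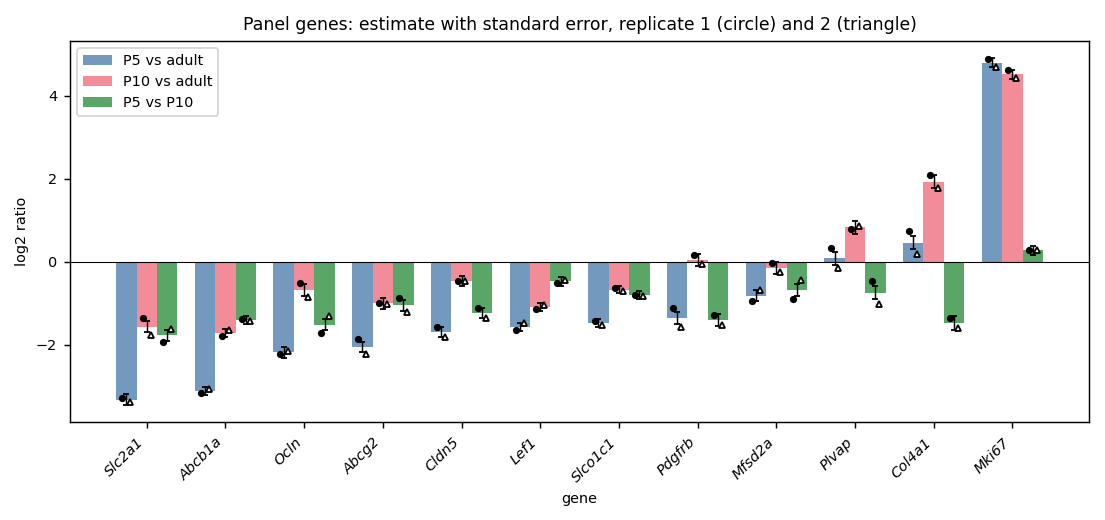
Log2 ratios of the 12 panel genes in the 3 comparisons (bars, y axis), with the standard error from the fit as error bars, replicate 1 as circles and replicate 2 as triangles. Abcb1a was lower at P5 than adult by 3.11 and lower at P10 than adult by 1.71, and Mki67 reached 4.80 at P5 and 4.52 at P10.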

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

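No test in this part was chosen after its result was seen. In the group of 4 P10 and adult arrays, 115 named genes and 33 list medians were examined for 1 array far from the other 3, which chance gives in about 1 in 20 groups of independent arrays. These 4 arrays are a dye-exchanged pair of each replicate, so that rate does not strictly hold. In all, 3 genes and no list met the limit. Ly6a had a log2 ratio of -2.39 on the P10/adult array of replicate 2 against -2.67 to -2.71 on the others, a gap of 0.873 of the whole range. Xdh had -2.77 on the same array against -3.24 to -3.28 (0.93 of the range). Timp1 had 2.19 on the dye-exchanged array of replicate 2 against 2.64 to 2.67 (0.932 of the range). All 3 kept their direction on every array.

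Some genes moved in opposite directions from the adult level at the 2 young ages. There were 51 genes (46 with a symbol) that were called lower at P5 and higher at P10 than in adults, and 43 (37 with a symbol) called higher at P5 and lower at P10. All of them also passed in the direct test of P5 against P10, which their 2 opposite calls make nearly certain. If the calls of both comparisons were independent, 425 and 600 genes would be in these groups, but both share the adult RNA and are not independent. Gja5 (-1.39 at P5 and 1.91 at P10), Fbln5 (-0.79 and 2.23, but -0.10 and 0.72 at its other probe, which did not pass at P5), Aoc3 (-1.40 and 1.48), Dhh (-1.17 and 1.59) and Gja4 (-0.71 and 1.69) had the largest differences among those lower at P5.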

How the results depend on the processing

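The background model fitted to every spot was the plan; the reported handling of the faulty spots replaced it after seeing the data, when that model was set beside it as an alternative and the analysis without the 2 arrays was added. Of 5703 values of named genes tested under alternatives, 5364 kept their side of the threshold, 330 lost and 9 gained it, and no called gene among those named changed sign; the background model fitted to every spot accounts for 124 of the losses in P5 against P10, 73 in P10 against adult and 3 in P5 against adult. With that model 2769 genes were higher and 2610 lower in P5 against adult, 101 and 152 in P10 against adult, and 0 and 0 in P5 against P10 (7065 at an unadjusted p below 0.05), while r between the log2 ratios of both fits was 0.983 to 0.987; the cause is the inflated background spread of 2 arrays, described with the processing. Without these arrays the counts were 852 and 1033 in P10 against adult and 3305 and 2306 in P5 against P10. Median centring gave 666 and 613 in P10 against adult and 4368 genes at least 2-fold different in P5 against P10; it moved the median of all genes from 0.056 to -0.12 there and from 0.094 to -0.074 in P5 against adult, and the share of higher genes from 56.6% to 46.6% in the latter. It moved 13 of 33 list medians in P5 against P10 and 7 in P5 against adult by over 1.5-fold, all downwards, and none in P10 against adult; 5, 4 and 1 changed sign, among them 1 called list, oligodendrocyte precursors in P5 against P10. The cause was not tested. Beyond the named genes, median centring kept the sign of 11038 of the 11647 called genes in P5 against adult. It kept that of 8545 of 9034 in P5 against P10 and of all 3843 in P10 against adult. In each comparison, 0 called genes were called in the opposite direction with it. Processed signals moved 4 list medians by over 1.5-fold in P5 against adult, 1 in P10 against adult (cell cycle, 2.28 to 3.44) and 1 in P5 against P10 (smooth muscle, -1.51 to -2.58). Across alternatives the erythroid median ranged from 3.21 to 4.80 in P5 against adult and fell as low as 1.55 in P5 against P10, and the cell cycle median ranged from 0.96 to 2.76 in P5 against adult. The replicate block is part of the reported fit; with no replicate block, P10 against adult had 4931 higher and 5037 lower genes from independent ratios and 5452 and 5459 from separate channels, where more degrees of freedom are counted, and no other count moved by over 1.5 times. The directly hybridised pair alone gave 2403 and 1597 in P5 against P10, with fewer arrays. Requiring also a 2-fold difference left 2795 and 1435, 600 and 590, and 1998 and 630. Feature Extraction's processed signals, which have no offset, gave 7340, 2452 and 5194 genes at least 2-fold different. With an estimated correlation 0 lists were called in P5 against adult, 0 in P10 against adult and 0 in P5 against P10, whereas fry called 23, 16 and 25. From 1 replicate alone, the genes at least 2-fold different numbered 4272 to 4562 in P5 against adult, 1372 to 1425 in P10 against adult and 2069 to 3434 in P5 against P10; 1 replicate leaves no degrees of freedom for a test. Signal over background limits genes near the offset, whose ratios are compressed.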

Other observations

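Tests of 3 explanations below, those of brain tissue of all other types, of neuronal RNA and of granulocytes at P10, were chosen only after the values they use had been seen, and the demand that they hold under every alternative was added after the P10 p-value for neuronal RNA was known. Blood cell markers outside the red cell lineage were examined with lists written after the erythroid and stefin results were known. Of 9 measured lymphocyte genes, 5 were higher at P5 than in adults (median 0.48), led by the T cell kinase gene Lck (1.81 ± 0.18, adjusted p = 0.0021) and the B cell receptor gene Cd79b (1.24 ± 0.13, adjusted p = 0.0026). Of 6 measured platelet and megakaryocyte genes, 3 were lower and 1 higher (median -0.33), with the platelet chemokine gene Ppbp at -2.77 ± 0.13 (adjusted p = 0.00057).

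Vascular lists were lower at P5 than at P10. Dye bias is argued against: P5 RNA was always labelled with Cy5, but the median dye term of the endothelial identity list was -0.09 on one slide and -0.04 on the other, against a median ratio of -1.30. Lists of other brain cell types did not rise alike at P5. The immature neuron median exceeded the astrocyte median by 1.19 (permutation p = 0.00067, 2-sided, over genes). Under the 16 alternatives the difference was 0.78 to 1.55, each with permutation p below 0.05. The genes of both lists may change with age within brain tissue, and the test was chosen after the values were seen. More brain tissue of all other types at P5 therefore cannot be excluded. A smaller share of vessel cells at P5 cannot be told apart from lower expression per cell: 8 transcripts made almost only by endothelial cells, all in the fixed lists, ranged from -1.38 to -0.64, a span of 6.06 standard errors, between the limits set for a common factor and against it. A rise of immature neurons alone, with expression per cell unchanged, would lower all other lists by about the same factor. The medians were -0.11 for astrocytes (standard deviation 0.53 over genes) and 0.18 for mature neurons (0.61), against -1.30 for endothelial identity. Myelinating oligodendrocytes were at -0.28 and perivascular macrophages at -0.61. Under that condition, which was not tested, the values argue against immature neurons alone as the whole cause. This argument was not among those fixed beforehand. It uses medians already reported, and no limit was set for it. A difference in age itself may account for the pattern and stays open.

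Erythroid and stefin genes were higher at P5 than in adults, and a candidate explanation is blood cells in the P5 fraction. Granulocyte markers, listed before they were tested, had a median of 0.54 at P5 against adult, but only 2 of 15 passed, and a minority passing had been set beforehand as counting against blood cells; S100a8 and S100a9 were at 0.91 and 0.88, against 5.31 to 6.19 for Cstdc5, Stfa1 and Stfa2. That bound was judged too weak only after this result: with a median standard error of 0.36 few could pass, and red cells can be present with few granulocytes, so the explanation stays open for the erythroid genes. For the stefin genes the values speak against granulocytes without excluding them. At P10, where 4 stefins were at 3.58 to 4.65, the granulocyte median was -0.26. In limma 0 of 15 markers were higher (0 at an unadjusted p below 0.05 as well). The bound added 2 times the median standard error of single markers, which is not a standard error of the list median. The sum stayed below 0.5 in the reported fit, but in only 14 of 16 alternatives. Expression by other cells of the young brain and age itself were not tested.

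Immediate early and stress genes were lower at both young ages than in adults. At P5 the immediate early list had a median of -2.07 against adult and the mature neuron list -0.42. The difference was -1.64 (permutation p = 6e-04, 2-sided, over genes, and below 0.05 under all 16 alternatives). Mature neuron genes varied, with 8 of 16 lower and 1 higher. More neuronal RNA in the adult fraction is argued against as the whole cause only if both lists follow neuronal RNA alike, which was not tested. At P10 it cannot be told apart, since the medians were -1.41 and -0.87, and the difference of -0.53 had permutation p = 0.047 in the reported fit but 0.05 or more under 10 of the 16 alternatives (permutation p from 0.004 to 0.09 over all 16). The endothelial identity median was -1.68 at P5 and -0.38 at P10 against adult. A smaller share of vessel cells may therefore contribute at P5. A stronger response of adult tissue to the isolation, which takes place after dissection, and an age difference in living vessels may contribute as well. No value here separates these possibilities.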
